A study of Mus musculus with 29 samples.

How the data were processed

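RNA from frozen subcutaneous white fat of mice was sequenced on a DNBSEQ instrument, which reads DNA nanoballs, in knockouts of the nuclear receptor coactivator gene Ncoa1 and in wild-type mice of both sexes. Per the labels, mice received CL316,243, an agonist of the β3-adrenergic receptor, at 0.5 mg/kg for 7 days by intraperitoneal injection, or saline (NaCl). The submitters' processing notes name HISAT2 2.0.4 and the mouse genome GRCm38/mm10. The program that made the expression values and the gene annotation are not given in the sources used here.

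The deposited values are FPKM (fragments scaled to transcript length and to the mapped reads of the library) in 2 tables made separately. The first table holds 24 columns and 18658 genes, and the second holds 5 columns and 17677 genes, of which 17536 are in both. Of these shared genes, 17428 had an identifier in the RefSeq annotation of GRCm38.p6, the source of the positions given here. A total of 26 symbols stored as dates and 1 symbol given to 2 gene identifiers were resolved by gene identifier. All 29 columns of FPKM were used.

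The series has 29 sample records, but 2 column names occur in both tables (Female_WT_NaCl replicate 3 and Male_KO_NaCl replicate 3) and 2 records have no column (Female_WT_NaCl replicate 2 and Male_KO_NaCl replicate 4). Columns with a repeated name were read as 1 mouse, and their log2 values were averaged for the fit, which leaves 27 mice. The group means in FPKM average the FPKM of such columns first, so their SD leaves out how far these columns lie apart. The treatment labels of the 15 CL samples count up over 7 different texts, of which 1 reads CL316,243, so samples were grouped by their titles. Groups held 4 mice, except 2 in Female_WT_NaCl and 3 each in Female_KO_NaCl, Female_KO_CL and Male_KO_NaCl.

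FPKM gives no read counts, so the absolute depth is unknown. The value of 1 read was estimated relative to the other libraries of its table from the smallest values of 159 genes in the first table and 155 in the second. Each first-table library had such a value in only 5 (Female_WT_CL replicate 3) to 32 (Male_WT_CL replicate 4) of these genes, so the estimate is rough. It ranged from 0.92 to 1.118, so as far as it tells depths were alike within a table. It does not compare depth between the tables. Summed FPKM per library ranged from 563255 to 707161, and 11499 to 12632 genes reached 1 FPKM. The gene with the highest value took 2.38% to 6.8% of a library's FPKM and the first 10 genes 10.6% to 19.6%.

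Genes with at least 1 FPKM in at least 3 mice, 13174 in all, were analysed as log2(FPKM + 1). The pseudocount of 1 makes changes of genes at a few FPKM smaller than their ratio. One limma fit (version 3.58.1, R 4.3.3, trend=TRUE, two-sided moderated test) had the mean of each of the 8 groups and the table as a covariate, set to 0.5 for the mice averaged over both tables, with 18 residual and 2.92 prior degrees of freedom. The second table holds Female_WT_NaCl replicates 1 and 3, Female_KO_NaCl replicate 1 and Male_KO_NaCl replicates 2 and 3, so levels of these 3 groups rest on this covariate. The 19 comparisons were CL against NaCl within each sex and genotype, knockout against wild type and female against male within the other factors, and their interactions. Adjusted p-values are Benjamini-Hochberg values over genes within a comparison, with a threshold of 0.05.

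Of 31 gene lists, 30 had at least 5 measured members. The mitochondrially encoded respiratory chain list had 0 of 11 genes in the tables and was left out. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, again with an estimated correlation, and by the rotation test fry. Across 19 comparisons this gave 570 tests, and p-values were adjusted over lists within a comparison. Of these, 260 passed with the preset correlation, 15 with an estimated correlation and 93 by fry, 86 of them shared by camera and fry.

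Named genes follow a rule. It always takes 11 genes (Ncoa1, Ncoa2, Ncoa3, Ucp1, Cidea, Ppargc1a, Dio2, Elovl3, Adrb3, Lep and Adipoq). For each CL effect it takes the 8 rising and 8 falling genes with the largest change among those past the threshold whose groups shared no values and whose higher group averaged at least 5 FPKM, with predicted genes, pseudogenes and immune receptor segments left out. For other comparisons it takes 5 and 5, for each list described up to 4 members with the smallest p, and where fewer than 3 genes passed, the 3 with the smallest p. Genes named outside the rule are said to be so. The groups, comparisons, lists, rule and most alternatives were chosen before the data were examined.

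The fit was tested on simulated data, normal noise around each gene's mean with that gene's spread within groups, with log2 changes of 0.5, 1, 2 or 4 added to 50 genes each. In the CL effect of wild-type males it called 48%, 82%, 98% and 100% of these, in wild-type females 6%, 56%, 92% and 96%, and in the genotype by treatment interaction of males 2%, 48%, 88% and 96%. Between 0.039% and 0.085% of the 12974 unchanged genes were called in the 4 designs simulated.

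Alternatives changed 1 choice at a time. They were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, a rescaling by trimmed means of log ratios (trims 0.3 and 0.05), quantile normalization, array weights, a replicate block, the mean of the lymphocyte, skeletal muscle or mammary list as a covariate, a log2 change of at least 1, a fit of only the groups compared, and each library left out. Others were chosen after seeing the data, namely no table covariate, the first table alone, 29 columns as 29 mice, and the first-table or the second-table column alone for the repeated names. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.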

Results

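Gene expression was measured by RNA sequencing in subcutaneous white fat of female and male mice, wild type or with a knockout of Ncoa1, after 7 days of the β3-adrenergic agonist CL316,243 (CL) or saline. The 29 deposited columns were read as 27 mice, because 2 column names occur in both tables. Columns that share a name may still come from different mice, as described at the end. Saline groups held 2 wild-type females, 3 knockout females, 4 wild-type males and 3 knockout males, and CL groups held 4, 3, 4 and 4 in the same order. Summed FPKM per library lay between 563255 and 707161. Relative depth was not settled within a table (value of 1 read 0.92 to 1.118) nor compared between tables, and absolute depth is unknown. The 2 tables behind the values were made separately, and both saline wild-type females, 1 saline knockout female and 2 saline knockout males have values in the second table. Differences below are log2 changes of FPKM + 1 with their standard error (SE). The added 1 makes them understate the ratio for genes at a few FPKM. They come from mean log2 values adjusted for the table. For the saline groups with second-table values they can therefore exceed the ratio of the mean FPKM given beside them. Group values are mean FPKM ± SD over mice. Genes given as examples of a list, and Acadl, Arntl, Dbp, Nnt and Otop1 where named elsewhere, were chosen after their values were seen.

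Ncoa1 itself (gene ID 17977, chromosome 12, 4247362 to 4477206 in GRCm38), a coactivator of nuclear receptors, was lower in every knockout column (1.47 to 2.9 FPKM) than in every wild-type column (4.93 to 9.16). Knockout means fell by 1.36 ± 0.16 in saline females (adjusted p 4.9e-05), by 1.12 ± 0.12 in CL females (2e-05), by 1.32 ± 0.14 in saline males (9.6e-06) and by 1.14 ± 0.11 in CL males (3.1e-06). Its call was lost in saline females when only the groups compared were fitted (adjusted p 1.0; 3.5e-06 to 1.0 over alternatives). Transcripts were thus reduced, not absent, and which exons the knockout removes is not given in the sources used here. In wild-type males Ncoa1 was also lower after CL (-0.35 ± 0.11, adjusted p 0.046), a call that 18 of 22 alternatives ended (adjusted p 0.0021 to 0.17). Its relatives Ncoa2 and Ncoa3 passed the test in no comparison.

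**Figure D1:**
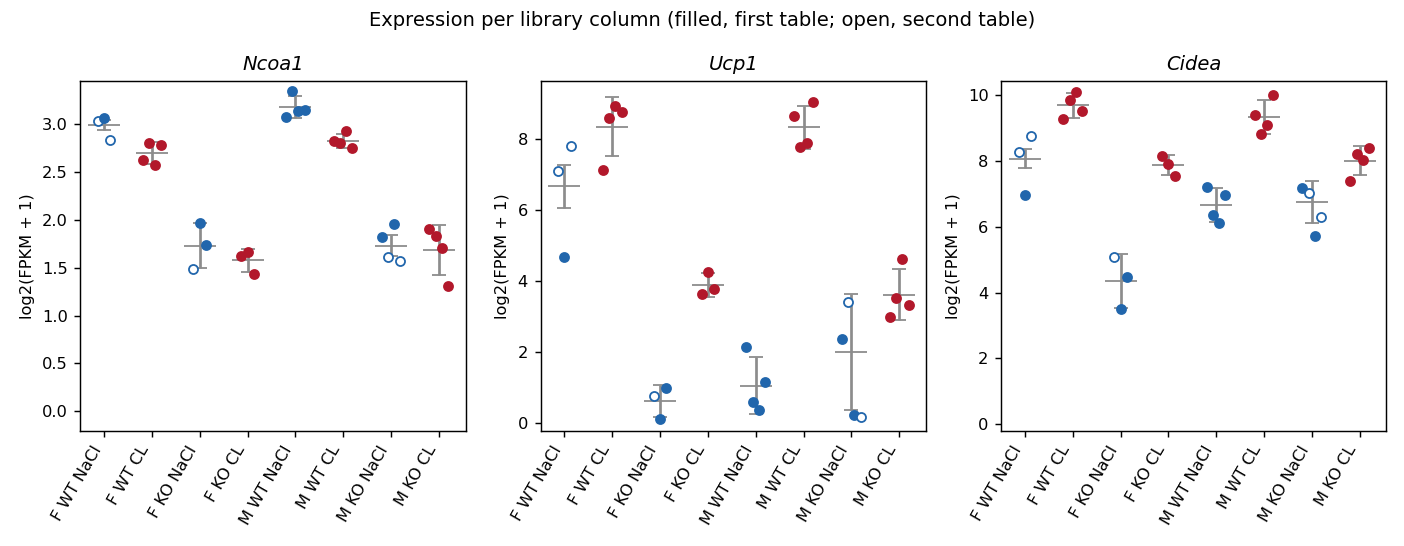
Values of Ncoa1, Ucp1 and Cidea as log2(FPKM + 1) in each column (vertical) by group (horizontal); blue marks saline and red CL, filled points are from the first and open points from the second table, and grey bars give mean ± SD over mice. Ncoa1 was at most 2.9 FPKM in knockouts and at least 4.93 in wild types, and Ucp1 under CL was lower in knockouts of both sexes.

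The response to CL in wild-type males asks how this white fat depot answers β3-adrenergic stimulation. Ucp1, the uncoupling protein of brown and beige adipocytes (gene ID 22227, chromosome 8, 83290348 to 83298456), went from 1.36 ± 1.42 FPKM (n = 4) to 347 ± 146 (n = 4), a change of 7.28 ± 0.54 with an adjusted p of 4.6e-08. With it rose Cidea, a lipid droplet protein of thermogenic adipocytes (gene ID 12683, chromosome 18, 67343564 to 67367794), by 2.68 ± 0.33, the fatty acid elongase Elovl3 by 4.02 ± 0.37, the cytochrome oxidase subunit Cox7a1 by 4.47 ± 0.57 and the fatty acid carrier Fabp3 by 5.89 ± 1.04. Every CL value of Ucp1 and Elovl3 lay above every saline value. Among the falling genes were Sfrp5, a secreted inhibitor of Wnt signals (-2.44 ± 0.52, adjusted p 0.0037), and the clock activator Arntl (-1.81 ± 0.27, 0.00013). Lep, the leptin gene, changed by -1.15 ± 0.29 (0.014).

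By pathway, all 30 nuclear-encoded respiratory chain genes rose, for example Ndufv1 by 1.26 ± 0.10, as did all 16 of the tricarboxylic acid cycle (camera adjusted p 3.4e-54 and 1e-32, each 0.0063 with an estimated correlation). Of 20 fatty acid oxidation genes, 17 rose and 3 did not pass, led by Acadl (1.75 ± 0.12, adjusted p 1.2e-08); adjusted over the list alone, 17 rose and 1 fell (camera adjusted p 1.4e-31, 0.0063 with an estimated correlation). Among 23 brown and beige adipocyte genes 18 rose and 1 fell, the transcription regulator Prdm16 (-0.43 ± 0.13, adjusted p 0.037, 0.00054 to 0.096 over alternatives and lost without Male_WT_CL replicates 1 to 4 or Male_WT_NaCl replicates 1 to 3, at 0.051 to 0.096), and 19 and 1 adjusted over the list alone (camera adjusted p 4.3e-22, 0.0063 with an estimated correlation). Glycolysis and glucose uptake had 11 of 17 genes risen, 11 also adjusted over the list alone, among them the glucose transporter Slc2a4 and the enolase Eno1 (1.31), with a camera adjusted p of 6.8e-11 and 0.034 with an estimated correlation. Fatty acid synthesis had 11 of 16 risen and 13 adjusted over the list alone, including Elovl6 (3.16) and Acacb (1.98), and cell division 9 of 13 and 13, including Rrm2 (1.15) and Mki67 (1.03). Their camera adjusted p-values were 1.9e-13 and 1.2e-10, but 0.084 and 0.18 with an estimated correlation.

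Groups that went down in these males were smaller. Of 16 stromal and extracellular matrix genes 6 fell and 8 adjusted over the list alone, such as Col6a3 (-1.03), and of 12 immediate early and heat shock genes 6 and 8, such as the chaperones Hspa1a (-1.68) and Hsph1 (-1.20). Macrophage genes fell in 3 of 15 cases and in 8 adjusted over the list alone, and adipokine and white adipocyte genes in 4 of 14 and in 6. Camera adjusted p-values ran from 0.00019 to 0.0092, and none held with an estimated correlation (0.18 to 0.44). In total 1485 of 13174 genes passed, 705 higher and 780 lower. Without Male_WT_CL replicate 4, whose skeletal muscle genes stood at a mean log2 value of 7.55 against 1.34 to 1.45 in the other 3, 902 passed. Without Male_WT_NaCl replicate 2 or 3 there were 956 and 960. The call of Lep was lost without Male_WT_CL replicate 1 or 4 or Male_WT_NaCl replicate 2 or 3 (adjusted p 0.052, 0.056, 0.055 and 0.061; 0.0054 to 0.061 over alternatives).

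In wild-type females CL also raised genes of fat burning, from a saline group of 2 mice. Cidea went from 294 ± 19.6 FPKM (n = 2) to 846 ± 214 (n = 4), by 2.06 ± 0.51 (adjusted p 0.031), and Elovl3 from 7.40 ± 1.48 to 34.8 ± 9.49, by 2.66 ± 0.57 (0.017). The peroxisomal thiolase Acaa1b rose by 2.32 ± 0.38 (0.0026), the lipoprotein lipase cofactor Apoc2 by 2.00 ± 0.39 (0.011), and Dbp, a transcription factor under clock control, by 3.10 ± 0.39 (0.00018). Ucp1 stood at 131 ± 9.1 FPKM under saline and 363 ± 155 under CL, a difference of 2.18 ± 0.84 that did not pass (adjusted p 0.13). The saline SDs average over 2 columns of replicate 3 that lie far apart, at 24.9 and 224 FPKM for Ucp1, 123 and 437 for Cidea and 1.29 and 15.6 for Elovl3, and are too small. The falling genes were led by the milk protein genes Csn2 (-6.22), Csn1s1 (-5.58) and Lalba (-3.69) and by Spp1, the osteopontin gene (-4.38 ± 0.84, adjusted p 0.01), whose direction turned with the first table alone (0.51). For Csn2 the saline columns read 113.8 FPKM in replicate 1 and 14860 and 0.25 in the second-table and first-table columns of replicate 3, so the 2 columns under that name differ and the errors of these genes are too small.

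Fatty acid oxidation genes rose in 14 of 20 cases, such as Acadl (1.24 ± 0.18, adjusted p 0.00075), and 16 rose and 1 fell adjusted over the list alone (camera adjusted p 2.2e-17, 0.19 with an estimated correlation). Respiratory chain genes rose in 14 of 30 and in 25 adjusted over the list alone, such as Ndufv1 (0.94 ± 0.16) (camera adjusted p 3.3e-21, 0.34 with an estimated correlation). Brown and beige genes rose in 4 of 23, or 5 adjusted over the list alone, and tricarboxylic acid cycle genes in 4 of 16, or 8 (0.0042 and 8.7e-10, but 0.46 and 0.38 with an estimated correlation). Of the stromal and matrix list 6 of 16 fell, or 11 adjusted over the list alone, such as Col3a1 (-1.98 ± 0.38, adjusted p 0.01), and of the macrophage list 2 of 15, or 9. These had camera adjusted p-values of 5.4e-08 and 3.4e-05, and 0.38 and 0.45 with an estimated correlation. The macrophage median, negative in the main fit, turned to 0.20 with only the groups compared.

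In all, 469 genes passed in wild-type females, 265 higher and 204 lower. The test passed 2240 with the first-table column of the repeated names, 93 with the second-table column and 0 with only the groups compared (2902 at an unadjusted p under 0.05 in limma's fit of all groups). The count was 86 and 132 without Female_WT_NaCl replicate 1 or 3, and 186, 307 and 879 without Female_WT_CL replicates 2, 3 and 4. The same 2 saline and CL replicates 2 and 3 each ended the call of Cidea when left out (0.096, 0.13, 0.063 and 0.056; 0.0011 to 1.0 over alternatives). Either saline mouse ended that of Elovl3 (0.064 and 0.09; 0.00019 to 1.0). Without Female_WT_NaCl replicate 3 the calls of Apoc2 (0.063; 8.3e-05 to 1.0), Ndufv1 (0.080; 1.6e-05 to 1.0) and Spp1 (0.10; 0.0059 to 1.0) were also lost. Ucp1 passed in 3 of 22 alternatives (0.0048 to 1.0). Among them was the first table alone, which leaves 1 saline wild-type female.

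In knockout females CL raised Ucp1, Cidea and genes of fatty acid oxidation. Ucp1 rose from 0.607 ± 0.461 FPKM (n = 3) to 14.2 ± 3.68 (n = 3), by 3.48 ± 0.67 (adjusted p 0.0031; 0.0011 to 0.13 over alternatives), Cidea from 21.6 ± 11.5 to 236 ± 48.3, by 3.71 ± 0.41 (1.6e-05), and Elovl3 by 4.28 ± 0.46 (1.3e-05). The apolipoprotein genes Apoc2 and Apoc4 rose by 2.40 and 2.38. Among falling genes were several of muscle, such as Fhl1 (-2.41 ± 0.65, adjusted p 0.028) and Tmod1 (-2.07 ± 0.57, 0.030). These moved with 1 library, Female_KO_NaCl replicate 2, in which skeletal muscle actin Acta1 read 14860 FPKM against at most 43.2 in the other female columns. Without it Fhl1 and Tmod1 no longer passed (0.18 and 0.30). Neither passed without Female_KO_CL replicates 1, 2 or 3 (Fhl1 0.096, 0.074 and 0.053, Tmod1 0.091, 0.069 and 0.075), with 0.00011 to 0.39 and 0.0028 to 0.30 over alternatives.

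Fatty acid oxidation genes rose in 19 of 20 cases, and in 19 adjusted over the list alone, such as Acadl (1.57 ± 0.14, adjusted p 3.9e-06) (camera adjusted p 5.6e-30, 0.021 with an estimated correlation). Risen were also 24 of 30 respiratory chain genes, or 28 adjusted over the list alone, 13 of 16 tricarboxylic acid cycle genes, or 16, and 10 of 23 brown and beige genes, or 14 (4.2e-26, 6.6e-15 and 6.2e-09, but 0.13 each with an estimated correlation). Lipid synthesis lists moved the same way. Of 16 fatty acid synthesis genes 7 rose, or 14 adjusted over the list alone, including Acacb (1.75 ± 0.26), of 14 fatty acid uptake and triglyceride genes 6 rose, or 8, including Agpat2 (1.81), and of 15 cholesterol synthesis genes 5, or 9, including Fdft1 (1.26). Their camera adjusted p-values were 1.5e-11, 3.3e-06 and 1.1e-06, and 0.15, 0.15 and 0.26 with an estimated correlation. Lipolysis genes rose in 4 of 14, such as the triglyceride lipase Pnpla2 (1.07), with 6 risen and 1 fallen adjusted over the list alone (0.00032, 0.20 with an estimated correlation). Skeletal muscle genes had a median of -4.95, with 0 of 15 past the test, 15 fallen adjusted over the list alone and an adjusted p of 0.37 with an estimated correlation. The test passed 978 genes, 677 higher and 301 lower (722 and 176 after quantile normalization). With only the groups compared it passed 2. Without Female_KO_CL replicates 1 or 2, or Female_KO_NaCl replicates 2 or 3, the count was 348, 460, 546 and 1677.

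In knockout males CL raised some thermogenic genes and lowered macrophage genes. Cidea went from 113 ± 42.4 FPKM (n = 3) to 265 ± 72.5 (n = 4), by 1.55 ± 0.41 (adjusted p 0.024), and Elovl3 by 1.97 ± 0.46 (0.013), while Ucp1, at 4.71 ± 4.80 and 12.6 ± 7.61 FPKM, did not pass (1.96 ± 0.68, adjusted p 0.085). It passed in 5 of 22 alternatives (0.016 to 0.39), among them without Male_KO_NaCl replicate 2 (0.042). Reep6, an endoplasmic reticulum protein gene, rose by 1.66 ± 0.16 (9.7e-06), and Ciart, a clock repressor, by 2.77 ± 0.48 (0.0027). Falling genes included the decoy interleukin receptor Il1r2 (-2.84 ± 0.50, adjusted p 0.0027), the lipid-associated macrophage receptor Trem2 (-2.65 ± 0.51, 0.0039) and the chemokine Ccl8 (-2.75 ± 0.65, 0.013). Of 15 macrophage genes 12 fell, or 13 adjusted over the list alone, such as Adgre1 (-1.81 ± 0.30) and C1qa (-1.69) (camera adjusted p 8.4e-13, 0.18 with an estimated correlation). Stromal and matrix genes fell in 7 of 16, or 13 adjusted over the list alone, such as decorin, Dcn (-1.44), and neutrophil and mast cell genes in 5 of 9, with 2 risen and 6 fallen adjusted over the list alone (5.4e-09 and 0.0078, but 0.34 and 0.37 with an estimated correlation).

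Fatty acid oxidation genes rose in 12 of 20 in knockout males, or 16 adjusted over the list alone, such as Acadl (1.07 ± 0.14, adjusted p 0.00041), respiratory chain genes in 7 of 30, or 12, tricarboxylic acid cycle genes in 6 of 16, or 8, and cell division genes in 4 of 13, or 10. Of 23 brown and beige genes 2 rose, and 6 rose and 1 fell adjusted over the list alone. Camera adjusted p-values were 4.1e-14, 3e-09, 5.2e-09, 1e-07 and 0.00046 in this order, and 0.18, 0.37, 0.34, 0.37 and 0.37 with an estimated correlation. The comparison passed 955 genes, 277 higher and 678 lower (443 and 628 after quantile normalization). It passed 214 without Male_KO_NaCl replicate 1 and 572 without Male_KO_CL replicate 4, the males of these groups with the highest skeletal muscle values (mean log2 7.46 and 5.42). With only the groups compared it passed 0 (2954 at an unadjusted p under 0.05 in limma's fit of all groups). Leaving out Male_KO_NaCl replicate 1 ended the calls of Trem2 (0.13; 0.00095 to 0.13 over alternatives), Adgre1 (0.054; 0.00026 to 0.15) and Ccl8 (0.075; 0.0024 to 0.18). Cidea did not pass without Male_KO_NaCl replicate 3 (0.12) or Male_KO_CL replicate 4 (0.069), with 0.0044 to 0.32 over alternatives, and Elovl3 did not without Male_KO_NaCl replicate 3 (0.064; 0.003 to 0.29).

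Between wild-type males and wild-type females, which share no library, 170 genes rose with CL in both and 64 fell in both, against 14.2 and 12.1 for independent lists of these sizes, and 0 went opposite ways. Wild-type and knockout males had 156 in common upward and 153 downward (14.8 and 40.1 for independent lists). Wild-type males and knockout females had 330 upward and 45 downward (36.2 and 17.8), and 8 went opposite ways. Acadl, Apoc2, Acaa1b and Elovl3 were among the genes higher after CL in both sexes, with Acadl past the test in all 4 groups.

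**Figure D2:**
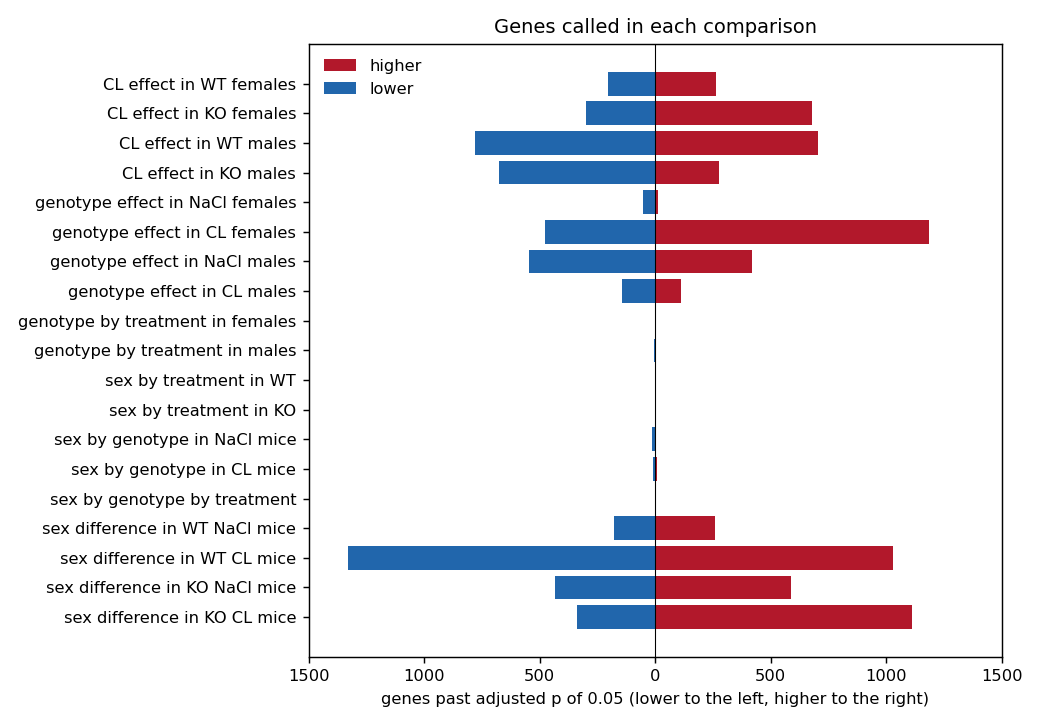
Number of genes past an adjusted p of 0.05 in each of the 19 comparisons, with genes higher to the right in red and lower to the left in blue. CL in wild-type males moved 1485 genes, and the interactions moved at most 17.

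**Figure D3:**
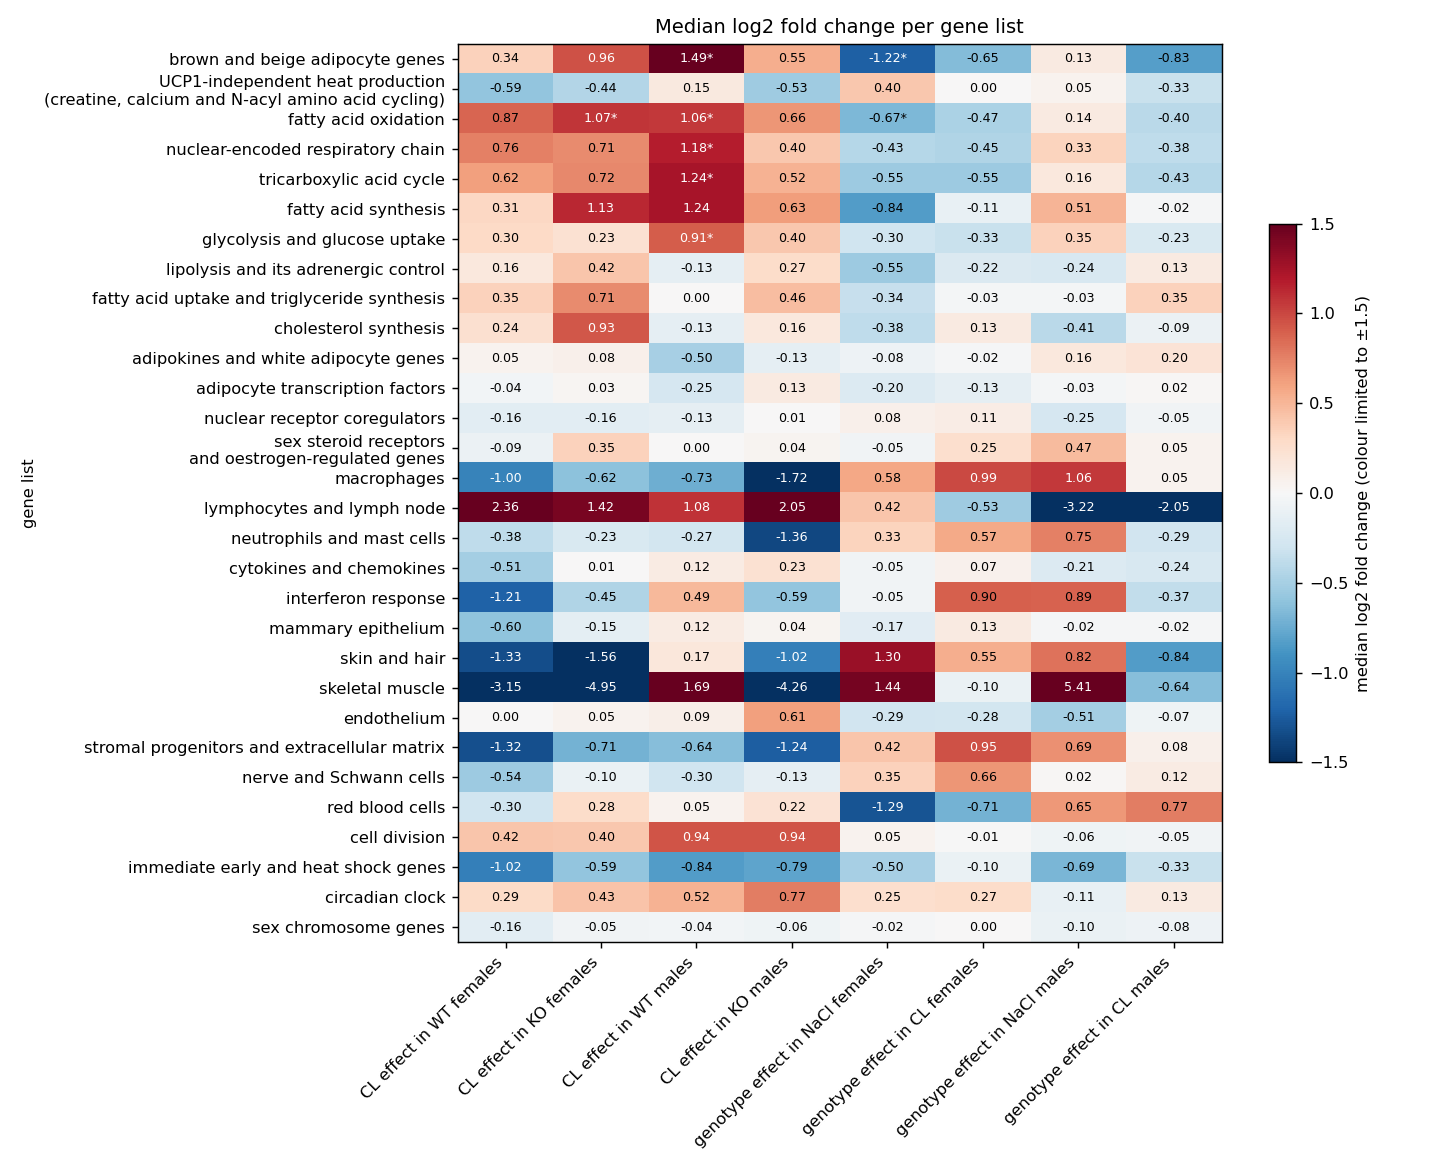
Median log2 change of each gene list (down the side) for the CL and genotype effects (across), red higher and blue lower; an asterisk marks an adjusted p under 0.05 with an estimated correlation. Fatty acid oxidation rose with CL in all 4 groups, with an asterisk in wild-type males and knockout females.

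Knockout against wild type under CL asks how expression differs between genotypes in treated mice. In males Ucp1, Cidea and other genes were lower in knockouts. Ucp1 was at 12.6 ± 7.61 FPKM in knockouts (n = 4) and 347 ± 146 in wild types (n = 4), a difference of -4.72 ± 0.54 (adjusted p 3.6e-05) with every knockout below every wild type. Cidea differed by -1.33 ± 0.33 (0.039) and the thioesterase Acot11 by -2.32 ± 0.41 (0.0035). S100b, a calcium-binding protein that adipocytes secrete toward nerve fibres, was at 6.74 ± 0.388 against 46.3 ± 3.62 FPKM (-2.61 ± 0.21, 1.8e-07), and the glutathione transferase Gstm6 at 0.677 ± 0.334 against 8.19 ± 0.847 (-2.47 ± 0.15, 2e-09). Higher in knockouts were Sugct, a mitochondrial CoA transferase (2.81 ± 0.38, 0.00026), and Slc27a1, a fatty acid transporter (1.33 ± 0.19, 0.00032).

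Of 23 brown and beige genes 8 were lower in these knockout males, or 15 adjusted over the list alone (camera adjusted p 1.6e-14, 0.091 with an estimated correlation). Fatty acid oxidation had 9 of 20 lower, such as Acaa2 (-1.09), and 1 higher, with 13 and 2 adjusted over the list alone. The higher one was Ehhadh (0.74 ± 0.17, adjusted p 0.029), lost without Male_KO_CL replicate 2 or Male_WT_CL replicates 1, 2 or 4 (0.12, 0.10, 0.068 and 0.078; 0.00012 to 0.12 over alternatives). In the tricarboxylic acid cycle 5 of 16 were lower, or 13 adjusted over the list alone, such as Suclg1 (-0.89), and in the respiratory chain 1 of 30, or 25. Camera adjusted p-values were 8e-08, 2.1e-11 and 1.6e-14, and 0.27, 0.23 and 0.27 with an estimated correlation. Fatty acid uptake and triglyceride genes went the other way, with 4 of 14 higher and 5 adjusted over the list alone, such as Cidec (1.10) (8e-08, 0.21 with an estimated correlation). The count was 256, with 111 higher and 145 lower (211 and 95 after rescaling by trimmed means, 181 and 104 after quantile normalization). It was 136 and 144 without Male_KO_CL replicates 2 and 4, and 121, 157 and 168 without Male_WT_CL replicates 1, 2 and 3. The call of Cidea was lost in 12 of 23 alternatives (0.0049 to 0.15), including without any 1 of the 4 knockouts (0.051 to 0.10) or without Male_WT_CL replicates 1, 3 and 4 (0.11, 0.063 and 0.13).

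CL-treated females showed the same direction. Ucp1 was at 14.2 ± 3.68 FPKM in knockouts (n = 3) against 363 ± 155 in wild types (n = 4), a difference of -4.46 ± 0.59 (adjusted p 0.00017), again with every knockout below every wild type. Cidea (-1.82 ± 0.36, 0.0056), Acot11 (-2.48 ± 0.44, 0.0031) and S100b (-1.89 ± 0.23, 6.8e-05) were lower too, as was Calca, which encodes calcitonin and CGRP (-3.27 ± 0.60, 0.0038). Among the higher genes was Dmbt1, a mucosal scavenger receptor (3.61 ± 0.60, 0.0017). Brown and beige genes were lower in 9 of 23 and higher in 1, with 13 and 1 adjusted over the list alone (camera adjusted p 9.4e-13, 0.15 with an estimated correlation). The higher one, the brown fat transcription factor Ebf2 (0.67 ± 0.20, adjusted p 0.036), did not pass without Female_KO_CL replicates 2 or 3 or Female_WT_CL replicates 1, 2 or 3 (0.14, 0.12, 0.084, 0.11 and 0.058; 0.004 to 0.19 over alternatives). Fatty acid oxidation had 14 of 20 lower and 1 higher, with the same numbers adjusted over the list alone, for example Acaa2 (-1.28), the respiratory chain 16 of 30 lower, or 22, for example Ndufv1 (-0.68), and the tricarboxylic acid cycle 8 of 16, or 9. Their camera adjusted p-values were 3.5e-12, 2.2e-19 and 1.5e-09, and 0.29, 0.29 and 0.30 with an estimated correlation.

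In these CL-treated knockout females macrophage genes were higher in 8 of 15, or 12 adjusted over the list alone, such as the mannose receptor Mrc1 (1.59 ± 0.35, adjusted p 0.0089), stromal and matrix genes in 9 of 16, or 11, such as Dcn (0.96), and nerve and Schwann cell genes in 3 of 9, or 6. Camera adjusted p-values were 2.6e-05, 1.5e-05 and 0.027, and 0.38, 0.41 and 0.33 with an estimated correlation. In total 1665 genes passed, 1187 higher and 478 lower, a split that was 690 and 676 after rescaling by trimmed means and 553 and 551 after quantile normalization. Fewer passed without Female_KO_CL replicates 1, 2 and 3 (980, 653 and 365) and Female_WT_CL replicates 2 and 3 (794 and 743), and 247 with only the groups compared. Leaving out Female_KO_CL replicate 3 ended the call of Mrc1 (0.052; 0.00065 to 0.052 over alternatives) and replicate 2 that of Dcn (0.055; 0.00038 to 0.055). With CL, 82 genes were lower in knockouts of both sexes and 22 higher in both (5.3 and 10 for independent lists), and 2 went opposite ways.

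Under saline, knockout females already had less of the thermogenic genes. Ucp1 was at 0.607 ± 0.461 FPKM (n = 3) against 131 ± 9.1 in wild types (n = 2), a difference of -5.76 ± 0.76 (adjusted p 0.00031; 4e-05 to 0.29 over alternatives). Cidea was at 21.6 ± 11.5 against 294 ± 19.6 (-3.47 ± 0.46, 0.00032). The wild-type means rest on the 2 unlike columns of replicate 3 (24.9 and 224 FPKM for Ucp1), all above every knockout. Otop1, a proton channel of brown fat, differed by -2.92 ± 0.36 (0.00015), Calca by -4.74 ± 0.77 (0.0033) and the thyroid hormone deiodinase Dio2 by -1.54 ± 0.31 (0.022). Dbp (2.41 ± 0.35, 0.00086) was higher, as was Nnt, the mitochondrial transhydrogenase (1.70 ± 0.26, 0.0015). Brown and beige genes were lower in 5 of 23, or 19 adjusted over the list alone (camera adjusted p 2.9e-29, 0.0033 with an estimated correlation), and fatty acid oxidation genes in 9 of 20, or 17, such as Acaa2 (9.1e-29, 0.013 with an estimated correlation). Acaa2 fell by 1.23 ± 0.21 (adjusted p 0.0064). In the respiratory chain 0 of 30 passed and 14 were lower adjusted over the list alone (2e-22, 0.10 with an estimated correlation); its median of -0.43 became 0.25 with the first table alone, which leaves 1 saline wild-type female.

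Of the 3 saline knockout females, replicate 2 stood apart with a skeletal muscle list mean of 11.5 on the log2 scale. The mammary list mean was 5.27 in wild types and 3.59 in knockouts, with 3 of 16 genes lower and 4 adjusted over the list alone (camera adjusted p 4.9e-06, 0.21 with an estimated correlation; median -0.17). That median turned to 0.27 without Female_WT_NaCl replicate 3, 0.07 without Female_KO_NaCl replicate 3 and 0.05 with the first-table column of the repeated names. Only 67 genes passed in saline females, 12 higher and 55 lower, and with only the groups compared 0 (1218 at an unadjusted p under 0.05 in limma's fit of all groups). The count was 29, 101 and 177 without Female_KO_NaCl replicates 1, 2 and 3, and 21 and 16 without Female_WT_NaCl replicates 1 and 3. Calca did not pass without Female_KO_NaCl replicate 1 (0.14) or Female_WT_NaCl replicate 3 (0.20), with 7.3e-05 to 0.46 over alternatives. Leaving out Female_KO_NaCl replicate 1 or Female_WT_NaCl replicate 1 ended the calls of Acaa2 (0.28 and 0.14; 0.00069 to 1.0) and Dio2 (0.27 and 0.14; 0.0084 to 0.32), both also without Female_WT_NaCl replicate 3 (0.054 and 0.24). Nnt did not pass without that mouse (0.075; 6.8e-06 to 1.0), and Dbp did not pass without Female_KO_NaCl replicate 1 (0.10; 0.00011 to 0.46).

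In saline males the largest differences between genotypes lay in other genes. Major urinary protein genes were higher in knockouts, such as Mup10 (5.84 ± 0.56, adjusted p 2.8e-06), from 7.11 ± 2.97 FPKM (n = 4) to 612 ± 297 (n = 3), and Mup2 (5.98 ± 0.61, 6.5e-06); these paralogs are nearly identical, so which of them the reads came from is uncertain. Sfrp5 (-4.09 ± 0.65, 0.00083) and Mest (-4.05 ± 0.48, 4.5e-05), genes linked to fat expansion, and Lep (-2.44 ± 0.37, 0.00047) were lower. Leptin transcripts stood at 121 ± 28.3 FPKM in knockouts and 589 ± 208 in wild types. Ucp1 was near the floor in both genotypes, at 4.71 ± 4.80 and 1.36 ± 1.42 FPKM (0.60 ± 0.68, adjusted p 0.60), and its direction turned without Male_KO_NaCl replicate 1 (-0.20) or with array weights (-0.79).

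Macrophage genes were higher in 7 of 15 in saline knockout males, or 12 adjusted over the list alone, such as C1qa (1.13, adjusted p 0.027), stromal and matrix genes in 4 of 16, or 5, such as Lum (1.28) and Dcn (1.24), and respiratory chain genes in 3 of 30, or 11. The sex steroid list, oestrogen receptors and their targets, had 4 of 10 higher, including Esr1 (0.93 ± 0.21, 0.011), and 1 lower, with 5 and 1 adjusted over the list alone. Camera adjusted p-values were 8.3e-09, 0.00011, 2.2e-09 and 0.0057, and 0.62 each with an estimated correlation. Adipokine and white adipocyte genes went both ways, 1 higher and 3 lower of 14 (4 and 3 adjusted over the list alone), with a median of 0.16 and a mean of -0.50 (camera adjusted p 0.82). Skeletal muscle genes had a median of 5.41 with 0 of 15 past the test, 12 adjusted over the list alone, and an adjusted p of 0.62 with an estimated correlation. The comparison passed 967 genes, 419 higher and 548 lower (625 and 406 after rescaling by trimmed means, 538 and 412 after quantile normalization). Without Male_KO_NaCl replicates 1 or 2 or Male_WT_NaCl replicate 2 the count was 353, 580 and 514. C1qa did not pass without Male_KO_NaCl replicates 1 or 2 or Male_WT_NaCl replicates 1 or 2 (0.13, 0.056, 0.058 and 0.059; 0.004 to 0.42 over alternatives).

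Whether the CL response itself differed between genotypes is the question of the interaction. In males it passed 7 genes, all with a lower log2 CL effect in knockouts than in wild types. For Ucp1 (-5.32 ± 0.87, adjusted p 0.021) the CL effect was 7.28 in wild types and 1.96 in knockouts, and for Mup10 (-4.58 ± 0.71, 0.015) it was 3.43 and -1.15. For Sult1e1, an oestrogen sulfotransferase (-1.81 ± 0.31, 0.021), it was -0.36 and -2.16, a larger fall in knockouts. Adjusted over the list alone, 29 of 30 respiratory chain genes had a lower CL effect in knockouts, though 0 passed over all genes (median -0.73, camera adjusted p 4.5e-30, fry 0.021, 0.13 with an estimated correlation). Brown and beige genes had 1 lower over all genes, Ucp1, and 10 lower and 1 higher adjusted over the list alone (6.2e-11, 0.13 with an estimated correlation). The interaction of Ucp1 ended in 9 of 30 alternatives (0.00075 to 0.20), among them leaving out Male_KO_NaCl replicate 1 (0.14), Male_WT_CL replicate 1 (0.061) and Male_WT_NaCl replicates 2 and 3 (0.057 and 0.065). The count was 13 and 4 without Male_KO_CL replicates 2 and 3, 3 without Male_KO_NaCl replicate 1, 2 without Male_WT_CL replicate 1 and 1 and 2 without Male_WT_NaCl replicates 2 and 3. Mup10 did not pass without Male_WT_NaCl replicate 2 (0.052; 0.0015 to 0.19 over alternatives), and Sult1e1 did not without Male_KO_CL replicate 4 (0.051), Male_KO_NaCl replicates 1 and 3 (0.13 and 0.052), Male_WT_CL replicate 1 (0.061) or Male_WT_NaCl replicates 2 and 3 (0.057 and 0.065), with 0.008 to 0.20 over alternatives.

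In females the interaction passed 3 genes, the milk protein genes Csn2 (6.19), Csn1s1 (5.34) and Lalba (3.68), which rest on the saline wild-type columns given above. For Ucp1 it was 1.30 ± 0.96 (adjusted p 0.93), so a smaller CL response of Ucp1 in knockout females was not shown. The interaction of Ucp1 turned to -0.34 with the first table alone, which leaves 1 saline wild-type female. Of the mammary list 3 of 16 were higher, and 3 adjusted over the list alone (median 0.25, camera adjusted p 3.9e-05, 0.60 with an estimated correlation). The median turned to -0.14 without Female_KO_CL replicate 1 and -0.07 without Female_WT_CL replicate 3. The count was 8 without Female_KO_NaCl replicate 3, 1 without Female_WT_CL replicate 1 or Female_WT_NaCl replicate 1, and 0 without Female_WT_NaCl replicate 3 or with a pseudocount of 0.1.

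Did the sexes differ in their response? Between female and male wild types the CL effect differed for 3 genes, Csn2 (-6.40), Csn1s1 (-5.58) and Lalba (-3.92), all lower in females, and for Ucp1 it differed by -5.09 ± 1.00 without passing (adjusted p 0.14), though it passed in 3 of 30 alternatives (0.0052 to 1.0). The count was 6 without Female_WT_CL replicate 1 and 0 without Female_WT_NaCl replicate 3. In knockouts 4 genes passed, all with a higher log2 CL effect in females than in males, Sult1e1 (2.09 ± 0.31, adjusted p 0.013), the sulfurtransferase Tst (1.89), the growth factor Gdf10 (1.82) and the aldehyde dehydrogenase Aldh3b2 (1.08). Leaving out single libraries gave 0 to 494 genes, the latter without Female_KO_NaCl replicate 3. All of Tst, Gdf10 and Aldh3b2 were lost without Female_KO_CL replicate 1 or 2, Female_KO_NaCl replicate 1 or 2, Male_KO_CL replicate 3 or Male_KO_NaCl replicate 1 or 2. Also lost were Tst and Gdf10 without Male_KO_NaCl replicate 3, Tst without Male_KO_CL replicate 2 and Aldh3b2 without replicate 4 (0.0028 to 0.70, 0.0064 to 0.78 and 0.0056 to 0.70 over alternatives). Sult1e1 was near 0 FPKM in females, so its value is that of the fall in knockout males (-2.16), and it did not pass without Female_KO_NaCl replicate 2 (0.058) or Male_KO_NaCl replicate 1 (0.074), with 0.00076 to 0.42 over alternatives. The difference between the sexes in the genotype by treatment interaction passed for Csn2 (6.35), Csn1s1 (5.44) and Lalba (4.01), while Ucp1 did not pass (6.62 ± 1.37, adjusted p 0.23). Ucp1 passed in 2 of 43 alternatives (0.0073 to 1.0), 1 of them without Male_KO_NaCl replicate 3, and single libraries left out gave 0 to 5 genes. The call of Lalba ended without most single libraries, at the most 0.44 without Male_KO_NaCl replicate 1 (0.0026 to 0.87 over alternatives).

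For the genotype effect under saline, 16 genes differed between the sexes, all with a lower genotype effect in females, and the median of all genes was 0.159 (0.003 after rescaling by trimmed means). Among them were Ucp1 (-6.36 ± 1.11, adjusted p 0.024) and Csn2 (-6.64). The brown and beige list (14 of 23 lower adjusted over the list alone, 1 over all genes, camera adjusted p 4.4e-18, 0.038 with an estimated correlation) and fatty acid oxidation (16 of 20 and 1, 4.1e-22, 0.040 with an estimated correlation) were lower too. Ucp1 did not pass in 11 of 28 alternatives (0.00045 to 1.0), among them without Female_KO_NaCl replicate 1 (1.0), Female_WT_NaCl replicate 1 (0.083) or 3 (0.11), Male_KO_NaCl replicate 1 (0.27) and Male_WT_NaCl replicate 2 (0.059) or 3 (0.053). Single libraries left out gave 0 to 39 genes.

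Under CL, 17 genes had a genotype effect that differed between the sexes, 8 higher and 9 lower in females, with a median of all genes of 0.171 (0.021 after rescaling by trimmed means). Reep6 (-1.58 ± 0.18, adjusted p 0.0004) went from 28.7 ± 0.957 FPKM in wild-type to 60.4 ± 10.6 in knockout males and from 65.9 ± 7.32 to 44.7 ± 3.25 in females, and it passed in every alternative run (3.6e-05 to 0.0035). Pnpla2, the first lipase of triglyceride breakdown, had -1.18 ± 0.20 (0.032), and Emp1, a membrane protein gene, 2.23 ± 0.43 (0.043), with 0.00023 to 0.18 and 0.0014 to 0.18 over alternatives. Both were lost without Female_KO_CL replicate 2 or 3 (at most 0.18), Female_WT_CL replicate 2 (0.082), Male_KO_CL replicates 2, 3 or 4 (at most 0.10) or any Male_WT_CL mouse (at most 0.10), and Emp1 also without Female_KO_CL replicate 1 (0.057) or Female_WT_CL replicate 3 (0.064). The count was 170 after rescaling by trimmed means, 19 higher and 151 lower, and 55 after quantile normalization (9 and 46). Each of the single libraries left out gave between 1 and 635 genes, the latter without Female_WT_CL replicate 4.

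Between the sexes themselves, epithelial genes were higher in females and genes of the Y chromosome in males in all 4 settings. Krt18, a keratin of glandular epithelium, was at 146 ± 19.7 FPKM in saline wild-type females against 0.242 ± 0.133 in males (6.79 ± 0.58, adjusted p 2.2e-07). The mammary epithelium list was higher in 15, 11, 13 and 13 of 16 genes in wild types under saline and CL and in knockouts under saline and CL. Adjusted over the list alone it was 16, 12, 13 and 13 (camera adjusted p 1.1e-43, 4e-20, 1.5e-19 and 1.7e-17, and 0.0013, 0.060, 0.034 and 0.079 with an estimated correlation). Of 8 sex chromosome genes 4 were lower in females each time, such as Eif2s3y (-5.06 in saline wild types), and 1, 1, 2 and 3 higher, with 3, 2, 4 and 4 higher and 4 lower adjusted over the list alone (1e-05, 9e-06, 4.5e-06 and 1.2e-05, and 0.091, 0.065, 0.039 and 0.079 with an estimated correlation). Under saline, wild-type females had more Ucp1 than males (5.11 ± 0.84, 0.0011, with 8.3e-06 to 0.69 over alternatives). They had less Lep (-2.43 ± 0.45, 0.0032), a call lost without Female_WT_NaCl replicate 3 (0.077, with 0.0004 to 0.79 over alternatives). All saline wild-type males are in the first table, and of the females only replicate 3 has a first-table column. Both differences therefore rest largely on the table covariate. Under CL, Ucp1 differed by 0.01 ± 0.54 (0.99). In saline knockouts Cidea (-2.29 ± 0.39, 0.00053), Pnpla2 (-1.01 ± 0.16, 0.00026) and Hsd11b1, which activates glucocorticoids (-2.87 ± 0.30, 2e-06), were lower in females. There, 14 of 20 fatty acid oxidation genes were lower, or 17 adjusted over the list alone, and 7 of 14 lipolysis genes, or 11 (1.7e-18 and 3.1e-10, 0.039 and 0.034 with an estimated correlation).

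Totals for these sex differences were 440 genes in saline wild types (260 higher in females, 180 lower), 2359 in CL wild types (1029 and 1330; 1410 and 907 after rescaling by trimmed means), 1024 in saline knockouts (589 and 435; 491 and 718, and 386 and 719 after quantile normalization) and 1451 in CL knockouts (1110 and 341; 835 and 660, and 742 and 805). With the mean of the mammary list, itself higher in females, as a covariate they were 11, 6, 6 and 9. Saline wild types gave 275 and 125 without Female_WT_NaCl replicates 1 and 3, and CL wild types 1440, 1288 and 1124 without Female_WT_CL replicate 2 and Male_WT_CL replicates 2 and 3. Saline knockouts gave 323 and 1765 without Female_KO_NaCl replicates 1 and 3 and 601, 655 and 596 without Male_KO_NaCl replicates 1, 2 and 3, and CL knockouts 746 and 655 without Female_KO_CL replicates 2 and 3 and 946 without Male_KO_CL replicate 4.

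**Figure D4:**
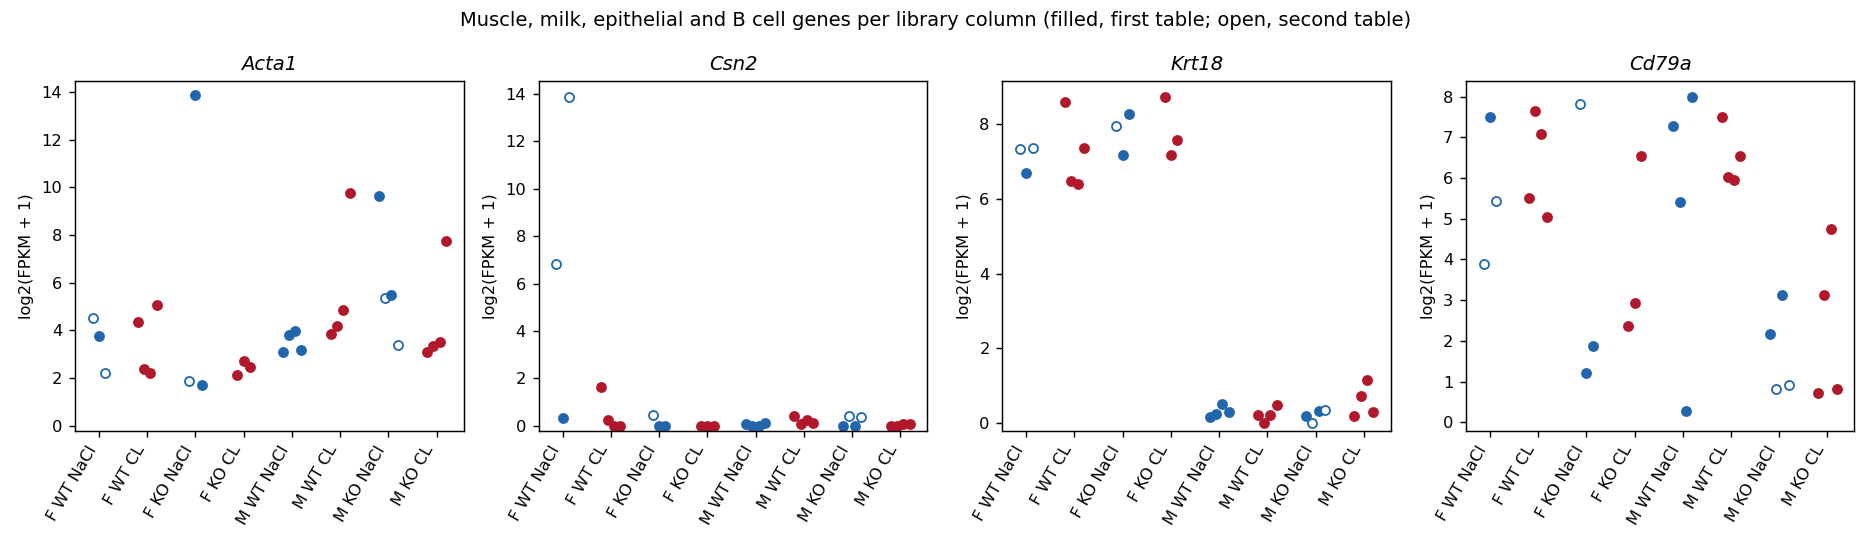
Values of marker genes of other tissues (muscle, milk, epithelium and B cells) as log2(FPKM + 1) in each column (vertical) by group (horizontal), 1 point per column, with blue for saline, red for CL, filled points for the first and open points for the second table. Acta1 reached 14860 FPKM in 1 saline knockout female, and Csn2 14860 in the second-table column of 1 saline wild-type female.

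Markers of tissues other than fat varied between single mice. The skeletal muscle list had a mean log2 value of 11.5 in Female_KO_NaCl replicate 2, 7.55 in Male_WT_CL replicate 4, 7.46 in Male_KO_NaCl replicate 1 and 5.42 in Male_KO_CL replicate 4; 0 of its 15 genes passed in any comparison, with medians from -6.4 to 5.41 and adjusted p-values of at least 0.27 with an estimated correlation. Lymphocyte and lymph node genes had list means from 0.5 to 5.79 among the columns and medians from -3.22 to 3.65, and 1 of 15 passed once, Glycam1, higher in females among CL knockouts (adjusted p 0.045), a call lost without Female_KO_CL replicates 2 or 3 or Male_KO_CL replicates 1 or 4 (0.17, 0.18, 0.11 and 0.12; 0.00053 to 0.98 over alternatives). Of the remaining lists, red blood cell, endothelium, skin and hair, and interferon genes had no call with an estimated correlation in any comparison.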

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

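Below, tests on a CL label and on DNA near Ncoa1 were written down before their results were seen, and all others were chosen after. The test on the second table replaced an earlier form of itself that had already been run.

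Under CL, Ucp1 was lower in knockouts of both sexes. Library scaling would have to remove the difference, but over both scalings and both sexes the smallest was -4.27, which argues against scaling. Fewer adipocytes in the knockout libraries would lower the genes of fatty acid uptake and triglyceride synthesis as well, and the lower of their medians in the 2 sexes was -0.03, which argues against that as the whole cause. Fewer brown or beige adipocytes, a direct genotype effect or a strain difference could give this, and bulk values do not separate them.

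In saline wild-type females Ucp1 stood at 137.25 FPKM in replicate 1 and at 224 in the second-table column of replicate 3, near or within the 139.19 to 489.72 of CL-treated wild-type females, and at 24.9 in its first-table column, below all of them. If second-table libraries read higher for Ucp1, the other second-table libraries should too, and their log2 differences from the first-table libraries of their groups were 0.21, 2.11 and -1.14. None reached the 3 units set for such a cause, but not all were under 1 either, so by the limits set this test cannot tell. The score of CL-responsive genes was at most 0.66 in these columns against at least 1.06 in CL-treated wild-type females. By the limit set this argues against a CL-treated mouse under a saline label. It is less clear for the second-table column of replicate 3, which had the 0.66. CL-treated mice of other groups scored as low as 0.73 (Female_KO_CL replicate 3), and the other saline columns at most 0.23 (Female_KO_NaCl replicate 2). No biological explanation was tested, and with 2 mice the pattern may rest on either of them.

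At an unadjusted p under 0.05, 99 genes differed in the same direction in all 4 genotype comparisons, 36 higher and 63 lower in knockouts. Not all passed the adjusted threshold in each. DNA of another strain around Ncoa1 would place them near it. They made up 5 of 66 genes within 20 Mb and 87 of 13061 elsewhere (odds ratio 12.2, 3.74 to 31.2, Fisher exact p 9.7e-05). None was close to Ncoa1, and all but Pqlc3 were predicted genes at 20240739 to 23969452. They may share a locus, so the p may be too small. Nnt, broken in some C57BL/6 substrains, differed by at least 1.14 each time, as an unlinked strain difference could give. For others, like S100b and Gstm6, regulation by Ncoa1 or a strain difference is possible.

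Among splits of the same mice into other groups, 1 of 35, the real one, gave as many genes for CL in wild-type males (1485, at most 0 in another split) and in knockout males (955, at most 166). The same 1 of 35 held for genotype in saline males (967, at most 3) and in CL males (256, at most 6). In saline males only knockouts have second-table values, so that grouping also follows the tables. Between the sexes it was 1 of 35 in CL wild types (2359, at most 389) and in CL knockouts (1451, at most 414). Chance is thus unlikely for each of these counts taken alone. However, 35 splits can go no lower than 1 in 35, and no correction was made for the number of comparisons. For genotype in CL females the share was also 1 of 35, but another split gave 1568 genes against 1665. A grouping other than genotype thus gave nearly as many, and the count alone does not set genotype apart. With 10 splits there are too few to tell for CL in knockout females (978, at most 5; 1 as high) and for the sexes in saline knockouts (1024, at most 992; 1 as high). For genotype by treatment in males 4 of 100 splits gave as many as the 7 genes, at most 151. For sex by treatment in knockouts 14 of 100 gave as many as 4 genes, at most 618, and for sex by genotype under CL 6 of 100 gave as many as 17, at most 945, so chance cannot be excluded. Splits with many times the real count point to a structure of the samples. In an interaction this may be effects of sex, genotype or treatment that a split moves into it, which was not tested.

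Single mice stood far from their group in list means on the log2 scale. Male_WT_CL replicate 4 had 0.8669 for mammary epithelium (others 0.17 to 0.25), 2.702 for skin and hair (others 0.87 to 0.96) and 7.547 for skeletal muscle (others 1.34 to 1.45). Skeletal muscle was also high in Male_KO_CL replicate 4, at 5.42 (others 1.12 to 1.25). Endothelium was low in Female_WT_CL replicate 2, at 4.452 (others 5.23 to 5.30). By chance the rule picks about 1 in 20 groups, so of 84 tests about 4.2 would be picked, and 5 were. That count does not weigh how far a mouse lay from its group. Only groups of 4 mice were tested. Female_KO_NaCl replicate 2 and Male_KO_NaCl replicate 1, with skeletal muscle means of 11.5 and 7.46, could therefore not be picked.

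Differences between the sexes brought up the interaction counts of 3 genes for treatment in wild types, 4 for treatment in knockouts, 16 for genotype under saline, 17 for genotype under CL and 3 for genotype by treatment.

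Of the 8 genes with the highest values among the 1122 in the first table alone, which were not fitted, 4 were higher in a CL library than in any saline library. The others had their highest value in a saline library, Female_KO_NaCl replicate 2. Gm1987 reached 61.46 FPKM in Female_KO_CL replicate 2 (highest saline value 18.17). The seminal vesicle genes Svs5, Svs4 and Svs6 reached 42.66, 38.31 and 15.42 FPKM in Male_KO_CL replicate 4 and 0 in saline libraries.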

How the results depend on the processing

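The tests in this part were chosen in advance except those on the tables and repeated columns, which were added after the values were seen. Directions were followed for named genes and for the medians of passing lists in CL and genotype comparisons, not for all called genes. Of these, no called gene and no list turned direction under either scaling. Ucp1 kept its calls in CL-treated knockouts of both sexes under every alternative run (adjusted p 2.3e-07 to 0.0027 in males and 3.6e-05 to 0.0091 in females). The rise of Ucp1 with CL in wild-type males was also kept throughout (1.1e-10 to 0.00014). Of 570 list tests, 260 passed by camera with the preset correlation, 15 with an estimated correlation and 93 by fry. Absolute depth is unknown, so genes at a few FPKM are measured poorly and their log2 changes are pulled toward 0. Values below are those that crossed a limit or turned direction, and unless the alternative tests fewer genes or samples, the cause was not tested.

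Replicate numbers do not pair the mice as far as the labels tell. With a replicate block the counts were 151 for CL in wild-type females, 40 for genotype in saline females, 1078 for genotype in CL females, 10 for sex by genotype under saline and 1 for sex by genotype under CL, and no other count moved by as much. Of 83 pairs of mice from different groups with the same number, the median correlation after removal of group means was -0.05 (-0.69 to 0.61), against 0.01 in 234 pairs with different numbers, and 3 of 27 mice correlated best with their own number.

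With a pseudocount of 0.1 the counts were 0 for genotype by treatment in females, 1 for sex by treatment in wild types, 0 for sex by treatment in knockouts and 0 for the 3-way interaction. Without a filter on low values they were 118 for genotype in saline females, 8 for genotype by treatment in females, 16 for sex by treatment in wild types and 10 for sex by treatment in knockouts. Further counts were 26 for sex by genotype under saline and 7 for the 3-way interaction. Keeping genes with a mean of at least 5 FPKM, which tests fewer genes, gave 52 for sex by genotype under CL, 224 for the sexes in saline wild types, 504 for the sexes in saline knockouts and 908 for the sexes in CL knockouts. After rescaling by trimmed means (TMM-type) the tests passed 1 for sex by treatment in knockouts and 170 for sex by genotype under CL. Quantile normalization gave 107 for genotype in saline females, 1104 for genotype in CL females, 2 for sex by treatment in knockouts and 28 for sex by genotype under saline. It also gave 55 for sex by genotype under CL. Directions turned there, to -0.19 for Ucp1 in the sexes in CL wild types.

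Array weights, which count single libraries less, gave 75 for CL in wild-type females, 447 for CL in knockout females, 3778 for CL in wild-type males and 383 for CL in knockout males. Further counts were 21 for genotype in saline females, 3078 for genotype in CL females, 485 for genotype in saline males and 1704 for genotype in CL males. This left 15 for genotype by treatment in males, 1 for sex by treatment in knockouts, 3 for sex by genotype under saline and 1774 for sex by genotype under CL. More were 347 for the sexes in saline knockouts and 4473 for the sexes in CL knockouts. Values of the other sign were -0.79 for Ucp1 in genotype in saline males, -0.03 for the tricarboxylic acid cycle median in genotype in saline males and -0.02 for the adipocyte transcription factors median in genotype in CL males. So they did to 0.38 for Ucp1 in the sexes in saline knockouts. With the lymphocyte list as a covariate there were 231 for CL in wild-type females, 482 for genotype in saline males, 8 for sex by genotype under saline and 31 for sex by genotype under CL. Here the sign changed, to 0.15 for Cidea in genotype in saline males and -0.03 for the sex steroid receptors and oestrogen-regulated genes median in genotype in CL males. The skeletal muscle list as a covariate gave 1145 for CL in wild-type females, 1438 for CL in knockout males, 585 for genotype in saline males and 0 for genotype by treatment in males. More were 6 for sex by genotype under saline and 592 for sex by genotype under CL. In this setting signs became -0.01 for the tricarboxylic acid cycle median in genotype in saline males, -0.03 for the glycolysis and glucose uptake median in genotype in saline males and -0.10 for the skin and hair median in genotype in saline males. Under the mammary list as a covariate, which itself differs between the sexes, there were 127 for CL in wild-type females, 224 for genotype in saline females, 65 for genotype by treatment in females and 63 for sex by treatment in wild types. It also gave 91 for sex by genotype under saline, 4 for sex by genotype under CL, 11 for the 3-way interaction and 11 for the sexes in saline wild types. Further counts were 6 for the sexes in CL wild types, 6 for the sexes in saline knockouts and 9 for the sexes in CL knockouts. Directions turned there, to -0.78 for Csn3 in the sexes in saline wild types, -0.25 for Wfdc18 in the sexes in saline wild types and -0.55 for Dio2 in the sexes in saline wild types. So they did to 0.69 for Ucp1 in the sexes in saline knockouts, 0.29 for Adrb3 in the sexes in saline knockouts and 0.09 for Adrb3 in the sexes in CL knockouts. Ncoa1, tested with it in females alone, stayed lower in both genotype comparisons.

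Leaving the table out of the model gave 1551 for CL in wild-type females, 1580 for CL in knockout males, 128 for genotype in saline females and 1502 for genotype in saline males. Further counts were 9 for sex by treatment in wild types, 161 for sex by genotype under saline and 1309 for the sexes in saline wild types. Values of the other sign were 0.09 for Cidea in genotype in saline males. From the first table alone, with fewer mice, came 1799 for CL in wild-type females, 499 for CL in knockout males, 202 for genotype in saline males and 0 for genotype by treatment in females. This left 4 for genotype by treatment in males, 12 for sex by treatment in wild types, 1 for sex by treatment in knockouts and 0 for sex by genotype under saline. More were 1 for sex by genotype under CL, 0 for the 3-way interaction and 665 for the sexes in saline knockouts. Here the sign changed, to 0.51 for Spp1 in CL in wild-type females, 0.10 for Folr1 in CL in wild-type females and -0.86 for the lymphocytes and lymph node median in CL in wild-type females. So they did to 0.25 for the nuclear-encoded respiratory chain median in genotype in saline females, 0.18 for the tricarboxylic acid cycle median in genotype in saline females and 0.52 for the glycolysis and glucose uptake median in genotype in saline females. So they did to -0.34 for Ucp1 in genotype by treatment in females, -0.10 for the brown and beige adipocyte genes median in genotype by treatment in females and -0.26 for the fatty acid oxidation median in genotype by treatment in females. So they did to -0.09 for the fatty acid synthesis median in genotype by treatment in females. Treating the 29 columns as 29 mice gave 2080 for CL in wild-type females, 111 for genotype in saline females, 0 for genotype by treatment in females and 4 for genotype by treatment in males. More were 0 for sex by treatment in wild types, 2 for sex by treatment in knockouts, 2 for sex by genotype under CL and 0 for the 3-way interaction. In this setting signs became -0.04 for Ucp1 in genotype in saline males. Taking the first-table column of the repeated names gave 2240 for CL in wild-type females, 31 for genotype in saline females, 468 for genotype in saline males and 0 for genotype by treatment in females. It also gave 0 for sex by treatment in wild types, 1 for sex by treatment in knockouts, 7 for sex by genotype under saline and 2 for sex by genotype under CL. Further counts were 0 for the 3-way interaction. Directions turned there, to 0.16 for the glycolysis and glucose uptake median in genotype in saline females and 0.05 for the mammary epithelium median in genotype in saline females. Their second-table column gave 93 for CL in wild-type females, 153 for genotype in saline females, 1 for genotype by treatment in females and 2 for sex by treatment in knockouts. Further counts were 35 for sex by genotype under saline, 5 for sex by genotype under CL and 0 for the 3-way interaction. Values of the other sign were -0.04 for the glycolysis and glucose uptake median in CL in wild-type females.

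Asking for a log2 change of at least 1 as well, a stricter rule, left 181 for CL in wild-type females, 250 for CL in knockout females, 260 for CL in wild-type males and 405 for CL in knockout males. This left 43 for genotype in saline females, 227 for genotype in CL females, 379 for genotype in saline males and 85 for genotype in CL males. More were 7 for sex by genotype under CL, 290 for the sexes in CL wild types, 452 for the sexes in saline knockouts and 492 for the sexes in CL knockouts. Fitting only the groups compared, with fewer samples for the variance and the table covariate, gave 0 for CL in wild-type females, 2 for CL in knockout females, 2628 for CL in wild-type males and 0 for CL in knockout males. More were 0 for genotype in saline females, 247 for genotype in CL females, 335 for genotype in saline males and 1 for genotype by treatment in females. Then came 1 for genotype by treatment in males, 0 for sex by treatment in wild types, 0 for sex by treatment in knockouts and 0 for sex by genotype under saline. More were 4 for sex by genotype under CL, 3 for the sexes in saline wild types, 1141 for the sexes in CL wild types and 228 for the sexes in saline knockouts. In this setting signs became 0.20 for the macrophages median in CL in wild-type females, -2.20 for the lymphocytes and lymph node median in CL in wild-type females and 0.09 for the interferon response median in CL in wild-type females. So they did to 0.15 for the immediate early and heat shock genes median in CL in wild-type females and 0.17 for Cidea in genotype in saline males.

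Leaving out each library in turn gave counts of 86 to 879 for CL in wild-type females, 348 to 1677 for CL in knockout females and 902 to 1246 for CL in wild-type males. The same omissions gave 214 to 1086 for CL in knockout males, 16 to 177 for genotype in saline females and 365 to 2207 for genotype in CL females. Counts then ran 353 to 795 for genotype in saline males, 121 to 309 for genotype in CL males and 0 to 8 for genotype by treatment in females. Among the rest they were 1 to 13 for genotype by treatment in males, 0 to 6 for sex by treatment in wild types and 0 to 494 for sex by treatment in knockouts. The same omissions gave 0 to 39 for sex by genotype under saline, 1 to 635 for sex by genotype under CL and 0 to 5 for the 3-way interaction. Counts then ran 125 to 396 for the sexes in saline wild types, 1124 to 2962 for the sexes in CL wild types and 323 to 1765 for the sexes in saline knockouts. Among the rest they were 655 to 1248 for the sexes in CL knockouts. Log2 values that turned sign in this way ran from -0.03 to 0.58 for the sex steroid receptors and oestrogen-regulated genes median in CL in knockout females, -0.06 to 0.67 for the cell division median in CL in knockout females and -0.03 to 2.26 for the skeletal muscle median in CL in wild-type males. Others ran from -0.52 to 0.03 for the glycolysis and glucose uptake median in genotype in saline females, -0.42 to 0.27 for the mammary epithelium median in genotype in saline females and -1.37 to 0.14 for the lymphocytes and lymph node median in genotype in CL females. Wider or narrower ranges were -0.20 to 1.5 for Ucp1 in genotype in saline males, -1.03 to 0.16 for Cidea in genotype in saline males and -0.02 to 0.12 for the adipocyte transcription factors median in genotype in CL males. Also turning were -0.08 to 1.44 for the interferon response median in genotype by treatment in females, -0.14 to 0.61 for the mammary epithelium median in genotype by treatment in females and -3.61 to 0.59 for the skeletal muscle median in genotype by treatment in females. Others ran from -0.15 to 0.59 for Ucp1 in sex by genotype under CL and -0.18 to 0.42 for Ucp1 in the sexes in CL wild types.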

Other observations

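Clock genes moved with CL in every group, tested after the values were seen. Dbp and Ciart, whose transcripts peak when the clock repressors are low, rose, and Arntl and Npas2, which encode activators of the clock, fell. Dbp rose by 3.10 in wild-type females, 1.12 in knockout females, 3.05 in wild-type males and 1.28 in knockout males (adjusted p 0.00018, 0.031, 1.1e-07 and 0.016). Arntl fell by 1.68, 1.70, 1.81 and 1.39 in the same order (0.032, 0.0037, 0.00013 and 0.016). Over alternatives the adjusted p reached at most 1.0, 0.17, 0.00036 and 0.30 for Dbp and 1.0, 0.22, 0.0022 and 0.16 for Arntl. Under saline Dbp was already higher in knockouts, by 2.41 in females and 2.62 in males (0.00086 and 5.1e-05). Of 14 clock genes, 5, 4, 6 and 4 rose with CL and 2, 2, 3 and 3 fell, and 5, 5, 7 and 8 rose and 3, 3, 3 and 3 fell adjusted over the list alone. The list passed in all but knockout females (camera adjusted p 0.045, 0.13, 0.030 and 0.024) and in none with an estimated correlation (0.38, 0.37, 0.18 and 0.34). The hour at which each mouse was sampled is not given in the sources used here.

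The major urinary protein gene Mup10 stood at 7.11 ± 2.97 FPKM in saline wild-type males and 612 ± 297 in saline knockout males, against 345 ± 98.5 and 747 ± 505 in the females. It has close paralogs, so which gene the reads came from is uncertain.

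The 2 columns named Female_WT_NaCl replicate 3 correlated at 0.9584, with 1029 genes (7.8%) over 2-fold apart. The second-table column of that name correlated more with that of Female_WT_NaCl replicate 1 (0.9725, 4.3%). The 2 columns named Male_KO_NaCl replicate 3 correlated at 0.9752 (4.0%), and the second-table column of that name at 0.9906 (0.8%) with that of Male_KO_NaCl replicate 2. Whether a repeated name stands for 1 mouse is therefore in doubt. The 2 records without a column belong to the same groups as the repeated names, so each such name may hold 2 different mice. Different mice of a group had a median correlation of 0.9736 (0.8464 to 0.9953) over 37 pairs.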
